A study of Mus musculus with 12 samples.

How the data were processed

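RNA was prepared from live mammary epithelial cells sorted on CD24 and CD49f into basal and luminal populations, per the labels' protocols, which name no step that removes leukocytes. Libraries were made with a stranded total RNA kit for low input (SMARTer Pico), per the labels' protocols. Reads were aligned with STAR 2.6.1b to the mouse genome GRCm38.p6 and assigned to genes with Subread 1.5, per the submitters' processing notes. The deposited table holds raw whole read counts per gene symbol, which the authors made with featureCounts 1.5.2 by largest exon overlap on GENCODE M17, per the file headers. Per the file headers the command set no strand option, so reads of a gene and of an overlapping gene on the other strand cannot be told apart. The deposited gene length column (summed exon length) was not used as a value. Gene coordinates are those of the deposited table, and 6 symbols span several chromosomes in it.

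The table holds 53735 symbols, of which 15946 had no count in any library. Total counts lay between 12459500 and 15069600 per library. Counting intervals are 95% intervals, a gene with 0 counts over a group was set to a floor of 3 counts over that group, and intervals and floors cover counting error only. No pair of the 12 libraries (66 pairs) was a duplicate, with a chi-square per degree of freedom of 28.6 or more over genes. CPM were scaled by TMM factors.

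Genes were kept by the filterByExpr function of edgeR 4.0.16 by group with a count minimum of 10 (CPM 0.728), which left 18236 genes. Counts were normalised by TMM and fitted in 1 quasi-likelihood model with robust spread over all 12 libraries and 4 groups (common biological coefficient of variation 0.450) in R 4.3.3. Contrasts were MMTVRANK minus WT in luminal and in basal cells, luminal minus basal in WT and in MMTVRANK, and the difference of the genotype effects. Every adjusted p for a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with a threshold of 0.05, and the SE is the log2 fold change over the square root of its F statistic. Groups followed the titles. The groups, the contrasts, the test, the gene lists, the rule for naming genes and the main alternatives were chosen before the data were examined.

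The genes named for each genotype comparison were the 10 highest and 10 lowest log2 fold changes among genes past the threshold. They also needed an average log2 CPM of 2 or more, a symbol that is not a predicted or clone name, and all 3 libraries of 1 genotype above those of the other. The same rule gave 5 and 5 genes for WT luminal against basal, and 5 and 5 for the difference of effects without the last condition. In addition 13 genes were named whatever their values (Tnfrsf11a, Cdkn2a, Cdkn1a, Mki67, Krt5, Krt14, Krt8, Krt18, Elf5, Kit, Esr1, Pgr and Prlr), and up to 4 members of a described list with the smallest p. Scarf2, and Col1a1, Lcp1, Lyz2, Ptprc, Ighm, Igkc and Trbc2 in the closing section, were picked after their values were seen.

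There were 28 gene lists with 809 entries and 751 distinct genes, of which 744 were in the table and 683 were tested, and 56 genes were in more than 1 list. The 27 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on the fit's design with a preset correlation of 0.01, adjusted over lists within each comparison. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over the list alone. For a test of leukocytes, 20 tested genes outside every list were taken by the symbols of 13 families (such as immunoglobulin chains, Fc gamma receptors and T cell receptors), chosen after the leukocyte markers had been seen; Ighmbp2, which shares a symbol stem alone, was among them.

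Measures of cell mixture, proliferation, RNA quality and total counts, 14 in each population and 28 tests in all, were compared between genotypes by two-sided exact permutation tests, whose smallest p is 0.1 with 3 libraries per group. None passed after adjustment, where the lowest value was 0.7.

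Groups share replicate numbers and the labels do not say what a number marks. Whether same-numbered libraries pair was checked on the correlation of their deviations from the group means over 10082 genes with an average log2 CPM over 3, before any fits were compared. For numbers 1, 2 and 3 the correlations were 0.525, 0.125 and 0.392 between luminal libraries of the genotypes, 0.277, 0.168 and 0.343 between populations in WT, and 0.278, 0.144 and 0.199 between populations in MMTVRANK. All are over 0.1, so the numbers were read as pairing these libraries, on the data alone. The deposited headers give each library 2 running numbers. By the first, the 2 populations of a genotype and replicate are consecutive, except for WT replicate 2. By the second they are consecutive throughout, WT replicate 2 included. The labels do not say what either number marks, so the pairing of the WT replicate 2 libraries is less sure.

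The scripts were tested on simulated counts with 200 changed genes. In the luminal genotype comparison (17523 genes) edgeR recovered 43.9% of the 4-fold and 3.09% of the 2-fold changes, with 1 false call of 47. In that comparison DESeq2 recovered 57.1% of the 4-fold changes with 21 false calls of 98, and limma-voom recovered 38.8% with 0 of 42. In the basal genotype comparison (17438 genes) edgeR recovered 48.9% of the 4-fold and 12.5% of the 2-fold changes with 0 false calls of 58, and in the WT population comparison (17451 genes) 51.5% and 9.57% with 4 of 63. In each of the 3 the seeded list was called, and 0 of 26 random lists were. Genes were simulated independently of each other. The simulation therefore cannot show false list calls that arise from correlation between genes.

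Alternatives were RLE normalisation, DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts, a stricter filter (over 1 CPM in 3 libraries), leaving out mitochondrial and structural RNA genes, fitting only the compared libraries, populations from the cell subtype field, leaving out both libraries with conflicting labels, the replicate number as a block, and leaving out each library in turn. Leaving out MMTVRANK luminal replicate 3 with both conflicting libraries, or with WT basal replicate 1, was chosen after seeing the data. Of 242 named or listed genes checked, 75 overlap exons of another gene. Among genes named in the text, Spp1, Prlr, Mcm7 and Cd74 overlap a gene on their own strand and Tspan8, Gadd45a, Axin2, Ezh2, Krt5, Krt8, Ccne2, Ciita, Lcp1, Mcm7, Wnt7b and Ppp2r2b one on the other strand, and their counts are uncertain to that extent. Overlaps of Ighm, Igkc and Trbc2 were not checked. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.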

Results

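Gene expression was measured by RNA sequencing in mammary epithelial cells of the mouse, sorted into basal and luminal populations by their surface levels of CD24 and CD49f. The cells came from MMTVRANK animals, in which a mammary tumour virus promoter drives the receptor Rank, and from WT animals. The 12 libraries form 4 groups of 3: WT basal, WT luminal, MMTVRANK basal and MMTVRANK luminal. For replicates 1, 2 and 3 the total counts were 13564100, 14413600 and 12459500 in WT basal and 13183900, 13240800 and 15069600 in WT luminal libraries. They were 15007700, 13757700 and 14155400 in MMTVRANK basal and 13488400, 13722400 and 14420100 in MMTVRANK luminal libraries (each rounded to 6 digits). The first principal component, 63.7% of the variance, placed the 6 libraries titled luminal between 79.4 and 160 and the 6 titled basal between −135 and −118. For the WT replicate 2 pair, the title and the cell subtype field of the labels name opposite populations. Both lay with the population in their titles, at 135 (luminal) and −119 (basal), and the titles were used. The labels do not say whether replicates are separate animals, so each test measures the spread between these libraries.

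Tnfrsf11a, the gene for Rank, was read first in every library because the transgene should raise it. It lies on chromosome 1 of GRCm38.p6 from 105781000 to 105848000 on the plus strand, with gene coordinates rounded to 6 digits here and elsewhere. In luminal libraries it stood at 319, 156 and 238 CPM (counts scaled to the library size) in MMTVRANK replicates 1, 2 and 3. WT luminal replicates 1 and 3 held 6.36 and 9.91 CPM (85 and 156 counts), but the library labelled WT luminal replicate 2 held 90.8 CPM (1280 counts). In basal libraries the MMTVRANK values were 415, 129 and 218 CPM, against 73.7 and 65.3 CPM in WT replicates 1 and 3. The library labelled WT basal replicate 2 held 158 CPM, above MMTVRANK basal replicate 2. Tnfrsf11a thus goes against the genotype labels of both WT replicate 2 libraries, and every genotype direction given here takes those labels as they stand. The counts do not separate transgene from endogenous transcripts. In luminal cells the log2 fold change, MMTVRANK over WT, was 2.74 (SE 0.89, n = 3 per group), which did not pass (edgeR quasi-likelihood test, adjusted p = 0.224). Without the library labelled WT luminal replicate 2 it rose by 4.87 with adjusted p = 0.0281, and over all alternatives the adjusted p ranged from 1.59e-27 to 0.720. In basal cells the value was 1.36 (SE 0.85, n = 3, adjusted p = 0.977) and did not pass either.

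**Figure D1:**
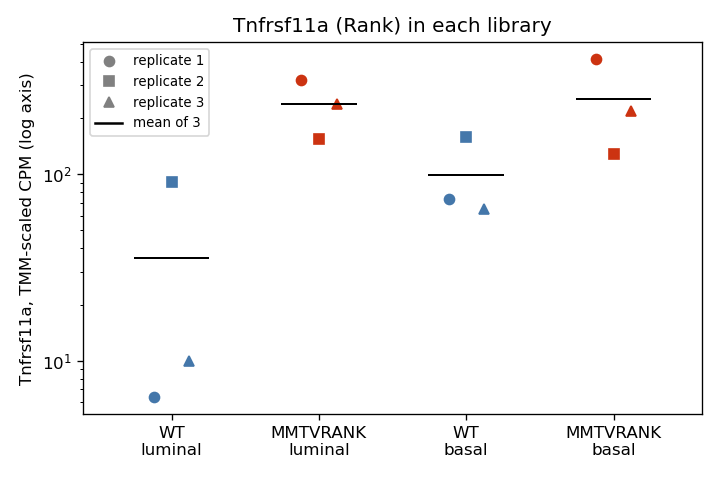
Tnfrsf11a in each of the 12 libraries, in CPM on a log axis, by group. Each point is 1 library with its replicate number. WT luminal replicates 1 and 3 sit at 6.36 and 9.91 CPM, and the library labelled WT luminal replicate 2 sits at 90.8 CPM, nearer to the lowest MMTVRANK luminal library at 156 CPM.

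The comparison of MMTVRANK with WT luminal cells asked what Rank activation changes in the luminal compartment. Of the genes with other than a clone or predicted name, 3 milk and alveolar genes fell furthest: Spp1 (osteopontin) had a log2 fold change of −6.32 (SE 0.77), Lalba (alpha-lactalbumin) −6.14 (SE 0.71) and Csn3 (kappa-casein) −4.69 (SE 0.60), n = 3 per group. Among those that rose were Tyms at 1.97 (SE 0.34), Pola1 at 1.82 (SE 0.31) and Skp2 at 2.65 (SE 0.45). Of 18236 genes, 17 rose and 29 fell at an adjusted p under 0.05, 46 in all, and 2183 had an unadjusted p under 0.05. DESeq2 gave 800 genes, 485 up and 315 down, and limma-voom 104, 12 up and 92 down, so the balance of directions depends on the tool. For each of the 46, all libraries of 1 genotype lay above all of the other, which held for 16.9% of all genes against 10% by chance. The 10% treats the luminal libraries as exchangeable and leaves out their pairing by number. The margin was narrow: 23 of the 46 had an adjusted p of 0.04 or more and 3 had one under 0.01. MMTVRANK luminal replicates 1, 2 and 3 had 24310, 24664 and 25591 genes with a count, against 19472, 23246 and 23144 in WT. Whether this difference bears on the calls was not tested.

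Among the genes that fell, Spp1 dropped from 235 ± 138 CPM in WT to 2.95 ± 2.65 CPM in MMTVRANK luminal cells (SD, n = 3; adjusted p = 0.0263). It lies on chromosome 5 from 104435000 to 104441000 and shares 309 bp with the gene model RP24-299A7.2 on the same strand, so its reads can be split. Lalba (chromosome 15, 98480400 to 98482700) dropped from 43.5 ± 18.2 to 0.607 ± 0.258 CPM with adjusted p = 0.00921. Csn3 went from 526 ± 292 to 20.4 ± 13.2 CPM (adjusted p = 0.0286). Btn1a1, the butyrophilin of milk fat globules, went from 252 ± 119 to 24.4 ± 6.52 CPM at a log2 fold change of −3.37 (adjusted p = 0.0387). Epb41l3, a membrane skeleton protein of the 4.1 family (chromosome 17, 69075700 to 69290000), fell from 26.2 ± 2.37 to 2.88 ± 0.846 CPM, a log2 fold change of −3.18 (SE 0.34, adjusted p = 0.00921). The Notch target Hey1 fell by 4.19 on the log2 scale, the channel gene Clic6 fell by 4.37, and the tetraspanin gene Tspan8 fell by 4.08, with 4 bp of the last overlapped by an opposite gene model. Col25a1 fell by 3.85, Pgm5 fell by 3.38 and Scarf2 fell by 2.52, the last at adjusted p = 0.00921 but outside the naming rule and picked after its value was seen. Adjusted p for Hey1, Clic6, Tspan8, Col25a1 and Pgm5 lay between 0.0286 and 0.0430. WT luminal levels were 19.9 ± 18.5 CPM for Hey1 and 8.02 ± 8.14 CPM for Col25a1, with WT luminal replicate 3 highest in both. Without it the value was −3.14 for Hey1, whose call ended, −2.63 for Col25a1 and −2.68 for Pgm5, and without MMTVRANK luminal replicate 1 it was −7.39 for Spp1, −5.40 for Csn3 and −5.06 for Tspan8.

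Among the genes that rose, the receptor tyrosine kinase gene Ephb2 had the highest log2 fold change of the named genes, 3.74 (SE 0.65, adjusted p = 0.0457), from 0.606 ± 0.399 to 8.34 ± 5.41 CPM (SD, n = 3). Pthlh, the parathyroid hormone-like hormone, followed at 3.31 (SE 0.59, adjusted p = 0.0457), from 0.321 ± 0.0523 to 3.27 ± 2.19 CPM. Without MMTVRANK luminal replicate 3 they had 3.05 and 2.57, and both calls ended. Skp2, which targets cell cycle inhibitors for degradation, rose from 1.66 ± 0.840 to 10.5 ± 3.28 CPM (adjusted p = 0.0430). Apcdd1, a Wnt inhibitor, rose by 2.62 and the Schlafen gene Slfn9 rose by 2.62, the latter from 18.4 ± 6.57 to 113 ± 47.3 CPM. Pola1, a DNA polymerase subunit, rose from 16.4 ± 0.563 to 57.7 ± 16.6 CPM, and Tyms, thymidylate synthase, from 6.99 ± 1.44 to 27.5 ± 5.99 CPM. Atad2 rose by 1.89, the p38 activating kinase gene Map2k6 rose by 1.81 and the adhesion gene Sdk2 rose by 1.97. Sdk2 stood at 183 CPM in WT basal cells, against 0.604 ± 0.153 CPM in WT and 2.38 ± 0.914 CPM in MMTVRANK luminal cells. In WT, 11 of the 46 genes were higher and 23 lower in luminal than in basal cells.

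Of 13 genes set in advance, none passed in luminal cells. The proliferation marker Mki67 stood at 88.0 ± 67.0 CPM in WT and 730 ± 285 CPM in MMTVRANK (SD, n = 3), a log2 fold change of 3.05 (SE 0.97, adjusted p = 0.212). Cdkn2a, which encodes p16 and p19, stood at 2.93 ± 1.38 and 8.11 ± 3.94 CPM, a value of 1.46 (SE 0.72, adjusted p = 0.456), and Cdkn1a, the p21 gene, had −0.14 (SE 0.19). The hormone receptor genes Esr1, Pgr and Prlr had −0.91, −1.34 and −1.07. The luminal keratin genes Krt8 and Krt18 had −0.60 and −0.67, the basal ones Krt5 and Krt14 had 0.93 and 2.42, and the progenitor genes Elf5 and Kit had −0.40 and 0.07. Adjusted p for these 9 genes ranged from 0.213 (Krt14) to 0.993 (Kit). All 46 calls kept their sign with each of the 12 libraries left out. Their separation by genotype all but fixes this in advance, so the kept signs say little about stability. Epb41l3, Lalba and Scarf2 alone were called each time. The count fell to 4, 3 and 5 without MMTVRANK basal replicate 1, 2 or 3, to 7 and 14 without WT luminal replicate 1 or 3, to 11 without MMTVRANK luminal replicate 3 and to 20 without WT basal replicate 1. It was 93 without WT basal replicate 3, and 103 (37 up, 66 down, 43 of them among the 46) with the replicate number as a block.

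**Figure D2:**
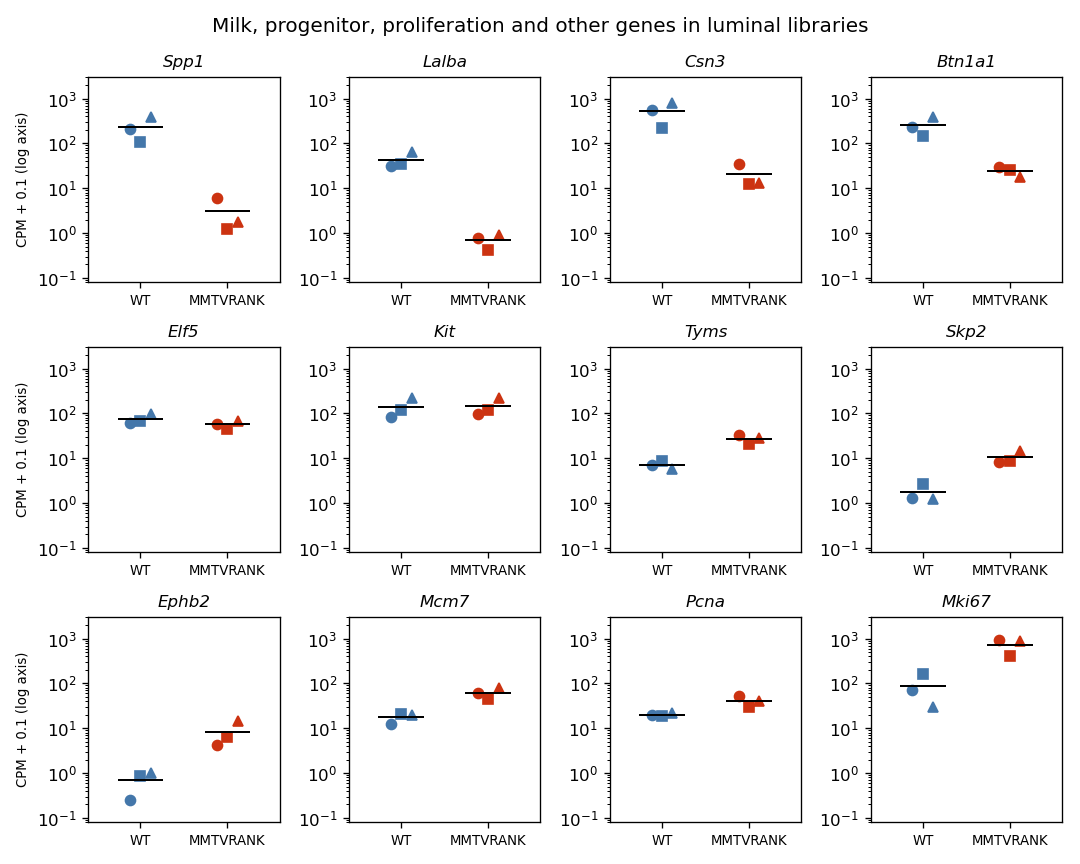
CPM of milk, progenitor, proliferation and other genes in the 6 luminal libraries, on a log axis, WT beside MMTVRANK. Points are libraries. Lalba averages 43.5 CPM in WT and 0.607 CPM in MMTVRANK, and Mki67 averages 88.0 and 730 CPM.

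Gene lists written down in advance were tested in luminal cells with camera, which asks whether a list moved against the other genes. With a preset correlation, 13 of 27 lists were called, 6 up and 7 down. None was called with an estimated correlation by camera (5 had an unadjusted p under 0.05), and 1, milk and alveolar genes, was called by fry. Of the proliferation list, 44 genes were tested: 1 rose over all genes (Tyms) and 40 rose adjusted over the list alone. All 44 values were positive with a median log2 fold change of 2.38, and the list went up at adjusted p = 6.62e-33, with adjusted p = 0.240 with an estimated correlation. Members short of the threshold over all genes included Mcm7 at 1.84 (adjusted p = 0.0911), Hells at 2.33 (adjusted p = 0.105) and Pcna at 1.02 (adjusted p = 0.109). Of the milk and alveolar genes, 25 were tested: 4 fell over all genes (Spp1, Lalba, Csn3, Btn1a1), 8 fell adjusted over the list alone, and none rose. The median was −0.95 and the list went down at adjusted p = 1.59e-10, with adjusted p = 0.0503 with an estimated correlation, and adjusted p = 0.0283 by fry. The luminal progenitor markers went down too (median −0.44, adjusted p = 3.29e-07, and adjusted p = 0.240 with an estimated correlation). Of these 25, Lalba, Csn3, Tspan8 and Hey1 fell, 6 fell adjusted over the list alone, and 9 values were positive.

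Hormone-sensing luminal markers had 20 of 25 negative values, a median of −0.99 and adjusted p = 2.27e-08, with adjusted p = 0.106 with an estimated correlation. None fell over all genes and 2 fell adjusted over the list alone: Cbr2 at −2.41 and Tph1, the latter at 460 ± 122.5 CPM in WT and 57.4 ± 24.7 CPM in MMTVRANK (SD, n = 3). Pan-luminal markers had 16 of 20 negative values and a median of −0.55, at adjusted p = 2.73e-06 and adjusted p = 0.106 with an estimated correlation. Lcn2 alone fell, from 542 ± 260 to 134 ± 25.5 CPM, over all genes and adjusted over the list alone. Basal and myoepithelial markers had 28 of 38 positive values, a median of 0.74 and adjusted p = 0.00340, with adjusted p = 0.837 with an estimated correlation. None of them passed by either adjustment, and without MMTVRANK luminal replicate 3 the test turned down (adjusted p = 0.837). The summed level of pan-luminal markers was 21276 ± 3842 CPM in WT and 13970 ± 2633 CPM in MMTVRANK (exact permutation test, two-sided p = 0.1, the smallest it allows, 0.7 after adjustment over 28 tests).

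The series also asks about senescence. Of 29 cell cycle inhibitors and senescence genes, Gadd45a fell over all genes, from 168 ± 29.7 to 74.7 ± 20.6 CPM (SD, n = 3), and none rose. Adjusted over the list alone, 4 rose and 2 fell, and the list as a group did not pass (median 0.31, adjusted p = 0.392). Lmnb1, a lamin gene whose loss marks senescent cells, had 1.65 (adjusted p = 0.0881) and the Polycomb gene Ezh2 had 0.85 (adjusted p = 0.0795). Of 50 senescence-associated secreted factors, Spp1 fell over all genes and 2 fell adjusted over the list alone. Their median was 0.49 and their mean 0.52 while the test pointed down, at adjusted p = 0.995. The p53 targets had a median of 0.06 (adjusted p = 0.489), with 0 of 35 passing over all genes and 3 rising adjusted over the list alone. The NF-kB targets, downstream of Rank, had 27 of 33 positive values and a median of 0.40, at adjusted p = 0.0433 and adjusted p = 0.837 with an estimated correlation. None of them passed by either adjustment, and Ccl20 had 6.04 (adjusted p = 0.226), at 23.8 ± 35.8 CPM in MMTVRANK. Without MMTVRANK luminal replicate 3, whose leukocyte markers summed to 703 CPM against 131 to 163 CPM in the other luminal libraries, the median was 0.02 and the call ended (0.630). Of 31 Wnt and Notch pathway genes, Hey1 fell over all genes, 5 rose and 2 fell adjusted over the list alone, and the group did not pass (median 0.29, adjusted p = 0.193). Nkd1 at 3.21 (adjusted p = 0.0720) and Axin2 at 2.69 (adjusted p = 0.0756), which overlaps an opposite gene model, led the positive values.

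Interferon response genes had 35 of 40 positive values in luminal cells, a median of 0.79 and adjusted p = 0.00185, with adjusted p = 0.837 with an estimated correlation. None passed by either adjustment, with Ifit2 at 2.32 (adjusted p = 0.189). Antigen presentation had 17 of 19 positive values and a median of 0.38, none passing, at adjusted p = 0.0433 and adjusted p = 0.837 with an estimated correlation. Its class II members Cd74 and Ciita had 4.89 and 4.67, and Cd74 stood at 212 ± 345 CPM in MMTVRANK (SD, n = 3). Without MMTVRANK luminal replicate 3, whose leukocyte markers summed to 703 CPM against 131 to 163 CPM in the other luminal libraries, the medians were 0.49 for interferon response and 0.15 for antigen presentation. Acute phase and antibacterial genes went down at adjusted p = 0.00369, with adjusted p = 0.484 with an estimated correlation, where the median was 0.10 and the mean −0.24. Of these 18, Hp and Lcn2 fell over all genes, and adjusted over the list alone 1 rose and 5 fell, with Hp going from 175 ± 21.7 to 47.3 ± 3.16 CPM. The lysosome list went down at adjusted p = 0.00155 (median −0.16, 0 of 37 passing, 3 falling adjusted over the list alone), with adjusted p = 0.484 with an estimated correlation. Immediate early and heat shock genes went down at adjusted p = 0.00222 (median −0.32), with adjusted p = 0.615 with an estimated correlation. Of these 30, Fosb fell, from 3718 ± 669 to 1545 ± 214 CPM, and 2 fell adjusted over the list alone. Pericyte markers had 8 of 9 positive values, 2 rising adjusted over the list alone, at adjusted p = 0.0134 and adjusted p = 0.724 with an estimated correlation. Their median was 1.48, or 1.28 with Kcnj8, at 0 counts in WT luminal libraries, set to its bound, while their summed level was 209 ± 12.4 CPM in MMTVRANK and 232 ± 18.3 CPM in WT (exact permutation test, two-sided p = 0.2).

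The other lists were not called in luminal cells. Leukocyte markers had 22 of 23 positive values and a median of 2.10 at adjusted p = 0.147, and −1.87 without MMTVRANK luminal replicate 3. EMT and matrix genes had a median of 1.07 (adjusted p = 0.329, 1 rising and 2 falling adjusted over the list alone) and endothelial markers 0.42 (adjusted p = 0.468). Fibroblast markers had a median of 0.26 and a mean of 0.27 while the test pointed down (adjusted p = 0.979). The squamous and stress keratins had a median of −0.12 and a mean of 0.16 (test down, adjusted p = 0.979), and adipocyte markers a median of 0.06 (adjusted p = 0.995). Medians were −0.04 for ribosomal proteins (adjusted p = 0.410), 0.07 for nuclear oxidative phosphorylation genes (adjusted p = 0.995) and 0.10 for cholesterol synthesis (adjusted p = 0.995, 1 rising adjusted over the list alone). The mitochondrially encoded genes had a median of −0.04 and a mean of −0.01 while the test pointed up (adjusted p = 0.979). Of the 13 called lists, proliferation, milk and alveolar genes, luminal progenitor markers, hormone-sensing luminal markers and pan-luminal markers were called with each library left out. Without WT luminal replicate 1 the calls ended for NF-kB targets (adjusted p = 0.164), basal and myoepithelial markers (0.0812), interferon response (0.0620), lysosome (0.157) and immediate early and heat shock genes (0.208), and without MMTVRANK luminal replicate 2 for NF-kB targets (0.0673), interferon response (0.0693) and acute phase and antibacterial genes (0.112). Without MMTVRANK luminal replicate 3 they ended for NF-kB targets (0.630), antigen presentation (0.741), pericyte markers (0.166) and basal and myoepithelial markers (0.837), without MMTVRANK luminal replicate 1 for acute phase and antibacterial genes (0.126), and for antigen presentation also without WT luminal replicate 2 (0.145) or 3 (0.252) or WT basal replicate 2 (0.0561) or 3 (0.0584).

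**Figure D3:**
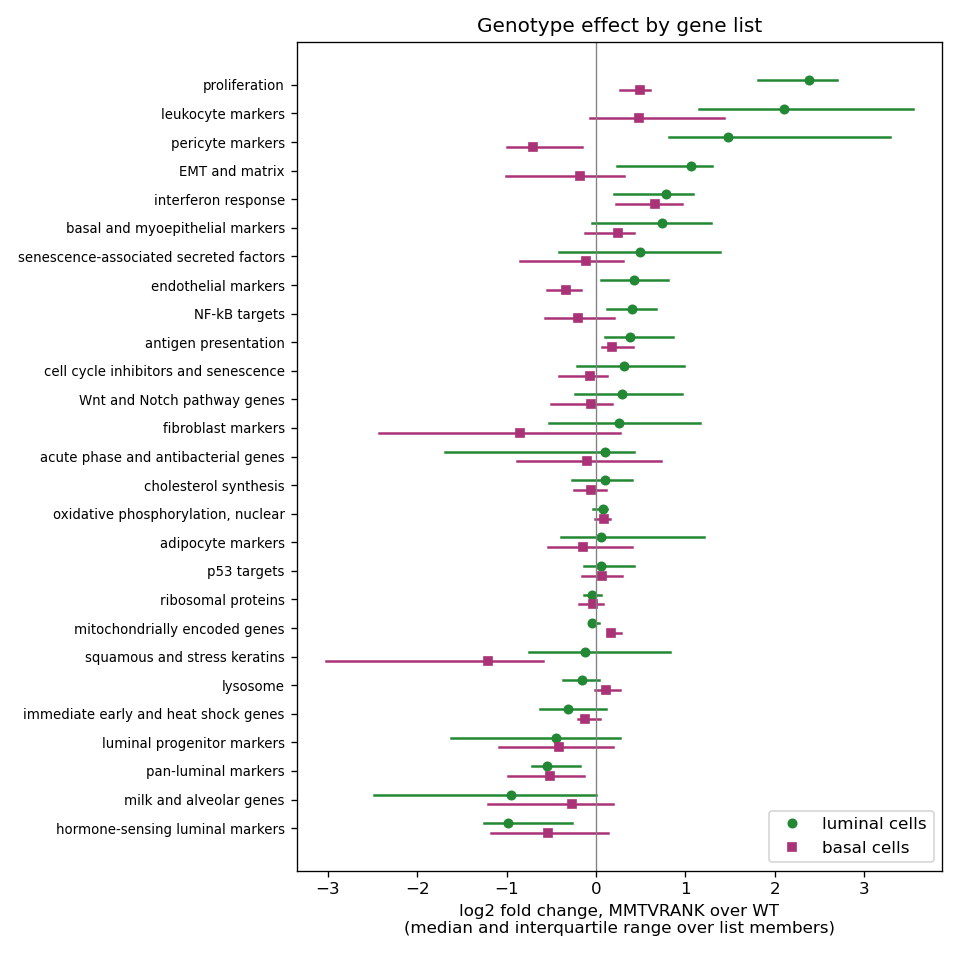
Median log2 fold change, MMTVRANK over WT, of each gene list in luminal and in basal cells. Points are medians over the tested members of a list. Proliferation stands at 2.38 in luminal and 0.50 in basal cells, and pan-luminal markers at −0.55 and −0.52.

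In basal cells 1 gene changed with the genotype: Crb3, which encodes an apical polarity protein, fell. Its log2 fold change was −2.97 (SE 0.29, n = 3 per group, adjusted p = 0.00351), from 2.95 ± 0.346 CPM in WT to 0.370 ± 0.0884 CPM in MMTVRANK (SD). These are 113 and 14 counts over each group, a ratio of 7.93 (95% counting interval 4.54 to 15.0), and luminal libraries held 40.7 ± 8.39 and 30.5 ± 2.88 CPM. Crb3 was thus far higher in luminal than in basal libraries. Whether its fall reflects fewer luminal cells in the MMTVRANK basal sort was not tested. Crb3 lies on chromosome 17 from 57059100 to 57065900. At an unadjusted p under 0.05 edgeR gave 986 genes, and libraries of the genotypes stood apart for 11.1% of genes against 10% by chance. DESeq2 gave 66 genes, 9 up and 57 down, and limma-voom none (991 at an unadjusted p under 0.05). Without MMTVRANK basal replicate 1 or 2 the count was 0 (838 and 856 at an unadjusted p under 0.05, with Crb3 at −2.83 and adjusted p = 0.0601 without the former, in a range of 1.08e-08 to 0.866 over all alternatives), and it was 2, 8 and 6 without WT basal replicate 1, 2 or 3.

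None of the 13 genes set in advance passed in basal cells. Cdkn1a came nearest, at 91.0 ± 7.84 CPM in WT and 43.2 ± 5.36 CPM in MMTVRANK (SD, n = 3), a value of −1.08 (SE 0.19, adjusted p = 0.246). Krt18 had −0.96 (SE 0.24, adjusted p = 0.652), Prlr −1.21 (SE 0.54) and Mki67 0.70 (SE 0.90). Krt5 and Krt14, the basal keratin genes, had −0.17 and −0.43. Camera with a preset correlation called 14 of 27 lists in basal cells, 2 up and 12 down, and no list was called with an estimated correlation (1 at an unadjusted p under 0.05) or by fry (1). Pan-luminal markers had 18 of 20 negative values, a median of −0.52 and adjusted p = 9.19e-09, with adjusted p = 0.0569 with an estimated correlation. None fell over all genes and 5 fell adjusted over the list alone, among them Krt18, Epcam at −0.72, Cldn4 at −2.90 and Cldn7 at −1.06. Proliferation had 39 of 44 positive values, a median of 0.50 and adjusted p = 9.55e-07, with adjusted p = 0.725 with an estimated correlation. No member passed by either adjustment, with Ccne2 at 1.23 and Cdk1 at 1.26. Interferon response had 36 of 40 positive values, a median of 0.66 and adjusted p = 0.000206, with adjusted p = 0.732 with an estimated correlation, and no member passed.

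The remaining lists called in basal cells all went down. Hormone-sensing luminal markers had a median of −0.53 (adjusted p = 0.00137, and adjusted p = 0.707 with an estimated correlation). Luminal progenitor markers had −0.42 (adjusted p = 0.00524, and adjusted p = 0.712 with an estimated correlation). Milk and alveolar genes had −0.27 (adjusted p = 0.00573, and adjusted p = 0.689 with an estimated correlation), with Btn1a1, at −3.30, and Ltf falling adjusted over the list alone. Btn1a1 stood at 2.93 CPM in WT and 0.286 CPM in MMTVRANK basal libraries, against 252 and 24.4 CPM in luminal libraries. Its genotype effects did not differ between the populations (edgeR quasi-likelihood test, unadjusted p = 0.975). Whether luminal cells in the basal sort account for the falls of the pan-luminal, hormone-sensing, progenitor and milk lists was not tested. NF-kB targets had −0.20 (adjusted p = 0.00524), senescence-associated secreted factors −0.12 (adjusted p = 0.0181), Wnt and Notch pathway genes −0.05 (adjusted p = 0.0424), squamous and stress keratins −1.21 (adjusted p = 0.00970) and pericyte markers −0.71 (adjusted p = 0.0161), each with adjusted p = 0.712 with an estimated correlation. Cell cycle inhibitors and senescence had −0.07 (adjusted p = 0.0161, and adjusted p = 0.712 with an estimated correlation), where Cdkn1a and Gadd45b, at −0.96, fell adjusted over the list alone. Fibroblast markers had −0.85 (adjusted p = 0.0224) and endothelial markers −0.34 (adjusted p = 0.0399), each with adjusted p = 0.732 with an estimated correlation. Adjusted over the list alone, Lgr5 at −1.57 and Wnt7b at −1.77 fell among Wnt and Notch pathway genes. Calls of 10 lists ended with some library left out: without MMTVRANK basal replicate 1 for NF-kB targets (0.217), senescence-associated secreted factors (0.394), Wnt and Notch pathway genes (0.221), fibroblast markers (0.0945), pericyte markers (0.0841) and endothelial markers (0.996, turned up), and without WT basal replicate 1 for Wnt and Notch pathway genes (0.379), cell cycle inhibitors and senescence (0.324), endothelial markers (0.210), pericyte markers (0.171), interferon response (0.140) and fibroblast markers (0.734, turned up). They also ended without WT basal replicate 3 for proliferation (0.968), NF-kB targets (0.344), senescence-associated secreted factors (0.0670) and endothelial markers (0.576), without WT basal replicate 2 for interferon response (0.101), cell cycle inhibitors and senescence (0.159) and squamous and stress keratins (0.168, turned up), without MMTVRANK basal replicate 2 for interferon response (0.783), cell cycle inhibitors and senescence (0.0919), Wnt and Notch pathway genes (0.0746) and pericyte markers (0.0798), and for Wnt and Notch pathway genes without WT luminal replicate 1 (0.0667) or 2 (0.0535).

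Whether the genotype acted differently in luminal and basal cells was tested as the difference of the genotype effects, luminal minus basal. Epb41l3 alone passed, with a difference of −3.74 (SE 0.46, n = 3 per group, adjusted p = 0.0420). It stood at 56.0 ± 27.4 and 82.5 ± 12.09 CPM (SD) in WT and MMTVRANK basal cells, and it fell in luminal cells. At an unadjusted p under 0.05 there were 1410 genes. Csn3 had a difference of −5.31 and adjusted p = 0.127. Among the 46, 29 had the same sign in basal cells and 6 of these had an unadjusted p under 0.05 there. Of these 6, Spp1, Lalba, Btn1a1 and Hp were higher in luminal than in basal cells in WT. They stood at 4.53, 0.324, 2.93 and 1.46 CPM in WT basal libraries. Ccdc88a was lower in luminal cells in WT, and Papln was not called between the populations. Across 11916 genes the luminal and basal genotype effects correlated at Pearson r 0.156 and Spearman rho 0.179, with 55.7% of one sign. These are values across genes, which are not independent replicates, and same-numbered libraries of the populations deviate together. Epb41l3 lost its call without MMTVRANK basal replicate 1 (−3.62, adjusted p = 0.161), 2 or 3, WT basal replicate 1, WT luminal replicate 1 or 2 or MMTVRANK luminal replicate 2, each leaving 0 genes. The count was 7 without MMTVRANK luminal replicate 1 and 3 without MMTVRANK or WT luminal replicate 3, and with the replicate block it was 0 (1500 at an unadjusted p under 0.05, Epb41l3 at −3.87 and adjusted p = 0.111, in a range of 1.68e-19 to 0.282 over all alternatives).

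For the difference of effects, camera with a preset correlation called 7 lists, 5 up and 2 down, with none by an estimated correlation or by fry (0 at an unadjusted p under 0.05 in both). No member of these lists passed over all genes. The proliferation list had 44 of 44 positive values and a median of 1.81 (adjusted p = 1.29e-10, and adjusted p = 0.748 with an estimated correlation). NF-kB targets had 29 of 33 positive values, a median of 0.75 and adjusted p = 0.000257, with adjusted p = 0.723 with an estimated correlation. Pericyte markers had a median of 1.64 (adjusted p = 0.000203), Wnt and Notch pathway genes 0.75 (adjusted p = 0.0143) and cell cycle inhibitors and senescence 0.55 (adjusted p = 0.0253), each with adjusted p = 0.723 with an estimated correlation. Lysosome had −0.34 (adjusted p = 0.000499) and milk and alveolar genes −0.07 with a mean of −0.52 (adjusted p = 0.0247), each with adjusted p = 0.723 with an estimated correlation. Adjusted over the list alone, Csn3 and Spp1 were lower among milk and alveolar genes, Ezh2 and Cdkn1a higher and Gadd45a lower among cell cycle inhibitors and senescence, and 4 higher and 2 lower among Wnt and Notch pathway genes. With the replicate block 4 lists kept their call: NF-kB targets, proliferation, lysosome and pericyte markers. Calls ended for Wnt and Notch pathway genes without MMTVRANK basal replicate 1 (0.0656), WT basal replicate 1 (0.103), WT luminal replicate 2 (0.113) or MMTVRANK luminal replicate 3 (0.122), for cell cycle inhibitors and senescence without MMTVRANK luminal replicate 1 (0.0615), WT basal replicate 1 (0.116), WT basal replicate 2 (0.0568) or WT luminal replicate 3 (0.106), and for milk and alveolar genes without MMTVRANK basal replicate 1 (0.153), WT basal replicate 2 (0.0612) or WT luminal replicate 3 (0.0677).

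Luminal and basal cells were compared within each genotype to give the reference for the sort. In WT 3284 genes were higher and 3656 lower in luminal cells (6940 in all, n = 3 per group). In MMTVRANK 2943 were higher and 3106 lower (6049 in all). Both genotypes shared 2326 genes higher and 2615 lower, against 530 and 623 for independent calls, and 2 genes went opposite ways. The genes named furthest up in WT luminal cells, by fitted log2 fold change, included Proc, the protein C gene, and Naip6. Each had 0 counts in WT basal libraries. Against a floor of 3 counts over the group they were at least 266-fold and at least 151-fold higher. These bounds do not settle their rank, since Ctse, Cxcl15 and Dscam, given next, had higher measured ratios. The secreted chemokine gene Cxcl15 had a log2 fold change of 10.06 (SE 0.95, adjusted p = 1.78e-05), Dscam had 9.39 (SE 1.58, adjusted p = 0.000871) and Ctse had 1957 counts against 1, a ratio of 1744 (95% counting interval 313 to 68929). WT luminal replicate 1 carried much of Ctse, and without it the ratio was 428 (76.4 to 16972), and without WT basal replicate 3, which held the 1 count, at least 405-fold. Cxcl15 had a ratio of 1069 (563 to 2339), 699 (368 to 1529) without WT luminal replicate 1 and 3076 (851 to 25405) without WT basal replicate 2. Dscam had 739 (288 to 2713), 472 (184 to 1735) without WT basal replicate 2 and at least 686-fold without WT basal replicate 3. The genes named furthest down, by fitted log2 fold change, each had 0 counts in WT luminal libraries. They included Lmo1, at least 652-fold lower (adjusted p = 2.28e-05), Ppp2r2b, at least 371-fold, Sh3rf3, at least 368-fold, and Nkain3, at least 340-fold. Scel, at least 417-fold lower, rested on the library labelled WT basal replicate 2 with 1106 counts against 9 and 1 in the other two, and without it was at least 5.85-fold lower and not called. Its call also ended without WT luminal replicate 1, 2 or 3 or MMTVRANK luminal replicate 3.

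Camera called 16 lists in each genotype, 9 up and 7 down, and with an estimated correlation 2: pan-luminal and basal markers. In WT, 36 of 38 basal and myoepithelial markers fell and none rose (median −7.57, adjusted p = 3.40e-38, and adjusted p = 0.0474 with an estimated correlation), such as Tagln at −7.48 and Tpm2 at −7.61. Pan-luminal markers rose for 16 of 20, with Krt18 at 5.84 and Cldn7 at 5.68 and Lcn2 the 1 that fell (median 2.98, adjusted p = 6.49e-19, and adjusted p = 0.0137 with an estimated correlation). Hormone-sensing luminal markers rose for 19 of 25 and fell for 1, with Foxa1 at 7.80 (median 4.48, adjusted p = 1.83e-11, and adjusted p = 0.0837 with an estimated correlation). Luminal progenitor markers rose for 16 of 25 and fell for 4, with Folr1 at 5.00 (median 2.85, adjusted p = 8.07e-05, and adjusted p = 0.405 with an estimated correlation). Milk and alveolar genes rose for 16 of 25 and fell for 1 (median 3.29, adjusted p = 6.26e-07, and adjusted p = 0.0837 with an estimated correlation). EMT and matrix genes fell for 17 of 27 and rose for 1 (adjusted p = 1.58e-06, and adjusted p = 0.402 with an estimated correlation), and fibroblast markers fell for 18 of 21 and rose for 1, with Col14a1 at −8.15 (adjusted p = 4.13e-06, and adjusted p = 0.405 with an estimated correlation). Adjusted over the list alone, the counts were 36 down for basal and myoepithelial markers, 16 up and 1 down for pan-luminal markers and 20 up and 1 down for hormone-sensing luminal markers. In MMTVRANK, 35 of 38 basal and myoepithelial markers fell (median −6.79), 17 of 20 pan-luminal markers rose (median 3.51), 18 of 25 hormone-sensing luminal markers rose, and 12 of 25 milk and alveolar genes rose. Of the 16 lists called in each genotype, 13 were called with each library left out. The calls that ended, at an adjusted p between 0.0526 and 0.253, were in WT interferon response (without WT basal replicate 1 or 2 or WT luminal replicate 2 or 3), pericyte markers (without WT basal replicate 1 or MMTVRANK basal replicate 3) and ribosomal proteins (without WT luminal replicate 1), and in MMTVRANK immediate early and heat shock genes (without MMTVRANK luminal replicate 2 or MMTVRANK basal replicate 3), interferon response (without MMTVRANK basal replicate 1 or MMTVRANK luminal replicate 2) and proliferation (without MMTVRANK luminal replicate 1 or MMTVRANK basal replicate 3).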

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

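The tests of basal cells, of a swap, of leukocytes by their markers and gene families, of progenitor loss and of dilution were chosen after the result was seen, and the other tests before.

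The genotype effect differed between luminal and basal cells for Epb41l3, at −3.74, and for the lists NF-kB targets (0.75), cell cycle inhibitors and senescence (0.55), proliferation (1.81), milk and alveolar genes (−0.0713), Wnt and Notch pathway genes (0.75), lysosome (−0.34) and pericyte markers (1.64, with Kcnj8 at its bound as well). Each passed a test of the difference itself, with camera at a preset correlation for the lists, but none of the 7 lists passed with an estimated correlation (adjusted p from 0.723 to 0.748) or by fry. With the replicate block Epb41l3 lost its call (−3.87, adjusted p = 0.111, in a range of 1.68e-19 to 0.282 over all alternatives) and 4 of the 7 lists kept theirs. Of 100 splits drawn from 200, the real one included, that regrouped genotype within both populations, 25 gave at least 1 gene and 92 gave at least 7 lists. The highest other counts were 7 genes and 20 lists, so chance cannot be excluded for either count. Of 3 other splits that exchange the genotypes of 1 replicate number in both populations, and so keep the pairs as the real one does, none gave a gene (real 1) and 2 gave at least 7 lists, the highest 16.

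For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. In luminal cells 1 of them, the real one, gave as many genes (46, highest other 5), and 7 gave as many lists (13, highest other 15). In basal cells 2 splits gave at least 1 gene, the highest other 12, and 2 gave at least 14 lists, the highest other 15. In WT 1 split gave as many genes between populations (6940, highest other 0) and 1 as many lists (16, highest other 15). In MMTVRANK 1 split gave as many genes (6049, highest other 0) and 3 as many lists (16, highest other 18). Every other split of these population comparisons put luminal and basal libraries on both sides. The population difference then counts as spread within a side, so their 0 genes say little about chance. Where the numbers pair, 3 other splits part all 3 pairs as the real one does. Their highest counts were 0 genes and 13 lists in luminal cells, 0 and 15 in WT and 0 and 15 in MMTVRANK, and the splits that do not part all pairs reached 5 and 15, 0 and 15, and 0 and 18. The basal split with 12 genes set MMTVRANK replicate 1, WT replicate 1 and WT replicate 2 against the other libraries, several times the real count, which points to a structure of the samples, and the luminal split with 5 genes grouped the same numbers. Camera with a preset correlation called many lists in these other splits too.

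Tnfrsf11a of the library labelled WT luminal replicate 2 stood at 90.8 CPM, against 6.36 and 9.91 CPM in the other WT luminal libraries. Basal cells would have to make up 90.8% of it, but its 38 basal markers stood at a median of 0.505% of their WT basal level (quartiles 0.138% to 2.42%), which argues against them. The lowest MMTVRANK luminal library held 19.1 times the mean of the other WT luminal libraries, which argues against a swap within the luminal libraries. On 100 genes chosen without it, the library lay at 0.398 between WT (0) and MMTVRANK (1), with a bootstrap interval of 0.333 to 0.466, against 0.397 (0.294 to 0.498) for MMTVRANK luminal replicate 1, 0.1704 and 0.0767 for the other WT and 0.750 and 0.892 for the other MMTVRANK libraries. These intervals resample genes and not libraries, and each library was placed on its own 100 genes between means of other libraries. The positions are therefore not on 1 scale. The intervals overlap and do not cover the spread between libraries, so the test cannot tell a wrong genotype label from a right one. By its first form, a comparison of positions without an interval, a wrong label would have been met by the margin between 0.398 and 0.397. The interval was added after that value was seen. On 100 genes chosen in the same way in basal cells, the library labelled WT basal replicate 2 lay at 0.789 (0.666 to 0.893), but WT basal replicates 1 and 3 at 0.529 and 0.835 and the MMTVRANK libraries between 0.575 and 0.664, so this position does not part the genotypes in basal cells and says nothing on that label. A biological difference between WT animals was not tested.

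Leukocyte markers summed to 703 CPM in MMTVRANK luminal replicate 3 and to between 131 and 163 CPM in the other luminal libraries. Of 23 markers 22 were highest in it, which restates that sum, with a median ratio of 16.5 and with Lcp1 at 182 against 120 CPM, Lyz2 at 134 against 0.707 CPM and Ptprc at 48.7 against 1.04 CPM. CD24 and CD49f alone were named for the sort, 10 of the 23 markers also averaged over 1 CPM in the other luminal libraries, and 1 is in another list. Of 20 leukocyte family genes outside every list, 12, or 60%, were highest in this library (95% interval 36.1% to 80.9%), with Ighm at 41.8 against 0.357 CPM and Igkc at 22.5 against 0.871 CPM but Trbc2 at 3.81 against 8.62 CPM, and 7 of the 20 averaged over 1 CPM in the other luminal libraries. Leukocytes in the sort may be a source of these values, but they and expression by the luminal cells cannot be told apart here: the interval lies above the 16.7% of chance, taking the genes as independent, but spans the bound of 50% set for leukocytes. Without the library the median of antigen presentation went from 0.38 to 0.15 (interval −0.04 to 0.35) and that of interferon response from 0.79 to 0.49 (0.28 to 0.84). Leukocytes and a change in the luminal cells cannot be told apart for either list, since both intervals span 0.5 of the value with the library; that leukocytes count as the source only when the whole interval lies under this bound was set after the values were seen, and by the first form, the median alone, antigen presentation met it. An effect of the genotype on immune genes stays open and untested.

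Milk and alveolar genes had lower values in MMTVRANK luminal cells, with a median of −0.95 over 25 genes, and of −5.41 over the 4 that passed over all genes; the list was called with a preset correlation and by fry but not with an estimated correlation (adjusted p = 0.0503). A loss of progenitor cells would lower their markers by about as much, and the median of luminal progenitor markers was −0.44 (interval −1.33 to 0.21). Dilution by other cells would lower pan-luminal markers alike, and their median was −0.55 (interval −0.68 to −0.21). These medians cannot tell apart loss of progenitors, dilution and lower expression per cell for the list. Both intervals span 0.5 of its median (−0.48). MMTVRANK luminal replicates 1 and 2 held 883 and 923 CPM of basal, 870 and 783 of fibroblast and 131 and 146 of leukocyte markers. WT luminal libraries held 1030 to 1156, 862 to 1314 and 143 to 163 CPM. These sums argue against dilution by such cells in those 2 libraries. Replicate 3 held 1750 CPM of basal and 703 CPM of leukocyte markers, so dilution stays open there. The 4 called genes fell further than either marker median, but they were picked by their calls and 2 of them, Lalba and Csn3, are progenitor markers too, so they decide nothing here. The milk and progenitor lists share 5 genes, so their medians are not independent. Loss of a smaller alveolar subset may be a further explanation, untested.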

How the results depend on the processing

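The alternatives that leave out MMTVRANK luminal replicate 3 with other libraries were chosen after seeing the data; the other tests were planned. Gene counts are for luminal, basal and difference of effects, main 46, 1 and 1. DESeq2 gave 800 (485 up, 315 down), 66 and 140, and no filter on low counts 1353, 349 and 776. Limma-voom gave 104 (12 up, 92 down, 29 of the 46), 0 (991 at an unadjusted p under 0.05) and 0 (1114). The strict filter gave 0 for the difference (1348), and only the compared libraries gave 7 and 0 (878). RLE gave 56 luminal genes (15 up, 41 down, against 17 and 29), and moved the median of all genes by under 0.1. Both conflicting libraries left out gave 81 (33 of the 46), 4 and 3; with MMTVRANK luminal replicate 3 out too, 4 basal and 13 difference genes. MMTVRANK luminal replicate 3 and WT basal replicate 1 left out gave 13 (7 of the 46), 3 and 0 (1069). With populations from the cell subtype field the counts were 0 (1222), 0 (1089), 0 (1333), 0 in WT (573) and 3 in MMTVRANK, with 8 basal and 13 difference lists; Ephb2 (−0.17), Pthlh (−0.62), Apcdd1 (−0.20), Sdk2 (−4.83) and Scel (6.63) reversed. The replicate block gave 103 luminal and 0 difference genes (1500) and 4 difference lists, and changed no other count of calls by over 1.5 times. In basal cells the numbers do not pair (0.404, −0.07 and 0.09 for numbers 1, 2 and 3; number 2 matched another number best, at 0.311), and the block left 1 gene and 15 lists. Estimated correlation called 0, 0 and 0 lists, and 2 and 2 between populations; fry called 1, 0 and 0. Tnfrsf11a passed without a filter (2.73 luminal, 1.38 basal) and in luminal cells without WT luminal replicate 2 (4.87), with both conflicting libraries left out (4.87) or those and MMTVRANK luminal replicate 3 (4.82). With each library left out, ranges were 3 to 93, 0 to 8 and 0 to 7 genes, 5776 to 6898 in WT and 4612 to 6415 in MMTVRANK; 10 to 16, 10 to 16 and 6 to 14 lists, 14 to 17 and 14 to 16 between populations; and 2.25 to 4.87 luminal and 0.82 to 1.88 basal for Tnfrsf11a. Tnfrsf11a apart, of 32 called named genes, 21 lost their call with some library out. Of 556 other values of named genes, 469 kept their side of the threshold, 70 lost and 12 gained a call, and 5 reversed. Of 5009 values of list members 112 lost and 193 gained a call and 0 reversed. A change of sign counted as a reversal only where the gene was called in the main fit or the alternative. Populations from the cell subtype field gave 27 of the 70 lost calls and all 5 reversals. Both libraries with conflicting labels lay with their titles, not with that field, on the first principal component. The cause of the other moves was not tested. Depth limits genes near the floor, such as Crb3 with 14 counts in MMTVRANK basal libraries.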

Other observations

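No test in this part was chosen after the result was seen. WT basal replicate 1 held the highest summed fibroblast markers, 7412 CPM, with Col1a1 at 638 CPM. MMTVRANK basal replicate 3 held 248 CPM of leukocyte markers. Mki67 stood at 161 CPM in the library labelled WT luminal replicate 2, against 72.5 and 30.1 CPM in WT luminal replicates 1 and 3, and at 533 CPM in the library labelled WT basal replicate 2, against 158 and 19.4 CPM. Mitochondrial rRNA took between 1.97% (WT luminal replicate 1) and 12.8% (MMTVRANK basal replicate 2) of counts. The summed proliferation list was 667 ± 289 CPM in WT and 3243 ± 1230 CPM in MMTVRANK luminal libraries (SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible). Erythroid markers, too few to test as a list, reached 139 CPM in MMTVRANK luminal replicate 3.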
